A study of Zea mays with 218 samples.

How the data were processed

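Leaf tissue of maize plants grown for 45 days in a greenhouse was sequenced. The series holds 218 libraries, of which 212 are RNA and 6 are DNA. In 16 lines the number of copies of 1 chromosome arm or segment was varied, and groups are named by that number (1D, 2D, 3D and 4D for 1, 2, 3 and 4 copies). Most lines carry a label beginning with TB, the usual name of a translocation between a maize B chromosome, a dispensable supernumerary chromosome, and an ordinary A chromosome; line Dp4 is labelled only by that name. A separate series varied whole chromosome sets (1X, 2X, 3X and 4X). Groups held 4 plants each, except the 4D group of Dp4 (3 plants), the triploids (2 plants) and the diploids compared with them (3 plants). Lines 3Sb and 5Lb had no 2D group of their own and were compared, in the deposited tables, with the 2D plants of line 1Sb.

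RNA was extracted with the mirVana kit and DNA with the DNeasy plant kit, per the labels' protocols. The submitters' processing notes name cutadapt 1.16, Bowtie2, TopHat2 and Cuffdiff without giving their roles; the genome build is not given in the sources used here, and coordinates are printed as the files give them. The 19 expression tables hold FPKM (fragments scaled to gene length and sequencing total) as 1 value per gene and group, with the p-value and q-value of each comparison, per the file headers; FPKM values of the plants behind each group are not analysed here. The smallest deposited p-value was 5e-05. The 3 DNA tables hold RPKM for 1 library per dose, per the file headers, whereas the plan had assumed DNA counts. No counting interval was therefore given for DNA, and ratios of RPKM were used as deposited. RNA depth is unknown because group FPKM keeps no read totals. FPKM is scaled to a total, so a change in the amount of RNA per cell is not visible in it, and a rise in some genes lowers the values of all others.

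Each expression table lists 40631 genes, of which 40270 are nuclear and 361 belong to the organelle genomes. None of the nuclear identifiers (0) matched the gene table supplied for this organism, whose assembly is Zm-B73-REFERENCE-NAM-5.0, while all 361 organelle identifiers did. The 31 gene lists fixed in advance could therefore not be run on nuclear genes, and no nuclear gene is given a name. Between 11008 and 13826 nuclear genes were listed at an FPKM of 0 in the 2D groups.

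Ratios were computed within each table as log2((FPKM of the dose + 0.5)/(FPKM of 2D + 0.5)) for nuclear genes with a mean FPKM of 1 or more over the table's groups. Medians of the list of genes raised across trisomies were taken without that minimum in the single comparison. The pseudocount makes changes of genes with low values appear smaller. Genes in the varied region are called cis, and genes on the other 9 chromosomes trans; the rest of the labelled chromosome was kept apart. The region ran from the tip of the labelled arm to the split of that chromosome's expressed genes with the largest difference, with at least 50 genes on each side and ratios limited to a size of 2. The split for 1D was taken from 3D and that for 3D from 1D, so that no region was chosen on the ratio measured in it. Counts of calls in both doses are an exception, as they used the region of 1D for both. In 10L18, 6Sa and Dp4 the DNA ratio set the region instead, from genes with a mean RPKM of 2 or more. A gene was placed with full dosage, no change or inverse change by whichever of the 3 levels (the copy ratio, 0, or the copy ratio with its sign turned) lay nearest on the log2 scale.

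The line, with 1 value each, was the unit of every test across lines: medians were tested with exact two-sided sign-flip permutation tests, and correlations with two-sided permutation tests of 100000 resamples. Since the plants of a group enter as 1 pooled value, these tests measure the spread between lines, and plant-to-plant spread enters only through the deposited p-values and q-values. For single genes, limma 3.58.1 (R 4.3.3) tested the mean log2 ratio across lines against 0 with a trend on mean expression, with a line left out where the gene lay on its varied chromosome, at least 8 lines per gene and Benjamini-Hochberg adjustment at 0.05. Genes called by the authors are those with a deposited q-value under 0.05. Other computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; plots were drawn with matplotlib 3.10.9. Groups, the tests, the rule for regions and the other settings to try were set before the data were examined, except for the tests and alternatives named below as chosen or added afterwards.

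The rule for genes to be named asked for names in the gene table and, where none were given, for the 2 identifiers with the largest and the 2 with the smallest mean log2 ratio among those past the threshold in each limma contrast and of 1 sign in at least 80% of lines. The limma step was tested on simulated ratios with the real spread of each gene between lines and 200 changed genes. For monosomies (19237 genes, 14 lines) it recovered 88% of genes changed by 1 log2 unit in either direction, 56% of those changed by -0.5 and 58% of those changed by 0.5, with 12 false calls. For trisomies (19546 genes, 16 lines) it recovered 92% at -1, 66% at -0.5, 58% at 0.5 and 100% at 1, with 9 false calls. For 3D over 1D (19401 genes, 14 lines) the shares were 88%, 66%, 36% and 80%, with 6 false calls. The search for breakpoints missed a simulated breakpoint by a median of 1 gene for a shift of -0.87, 3 genes for 0.48 and 9.5 genes for 0.28, over 2000 genes and 200 runs each. With no simulated shift, the sign-flip test gave a p under 0.05 in 4.75% of runs for 14 lines and 4.25% for 16 lines.

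Alternatives covered the minimum FPKM (0.1 and 5), the pseudocount (0.05 and 2), the mode in place of the median, other definitions of the region and of trans genes, centring on each line's trans median, a robust variance trend, a q-value of 0.01, the length of the region in place of its gene number, leaving out 3Sb and 5Lb, and leaving out each line in turn. The columns of the 3X table that hold spreadsheet errors were not used. Analyses that need values per plant were not made.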

Results

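The data describe leaf transcriptomes of maize plants in which 1 chromosome arm or segment was present in 1 to 4 copies, or in which whole chromosome sets were varied. Of the 16 lines with a varied region, 14 had plants with 1 copy (monosomy), 16 had plants with 3 copies (trisomy) and 4 had plants with 4 copies (tetrasomy), each set against plants with 2 copies. Another series compared haploids, triploids and tetraploids with diploids. Each group value is the authors' FPKM over usually 4 plants, so errors below are standard deviations (SD) between lines, and the read depth of the RNA libraries is unknown. All log2 ratios are on the scale of FPKM plus a pseudocount of 0.5.

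DNA of 3 lines lay close to the copy number that the labels give. In line 10L18 the DNA of 3D plants was 1.51 times that of 2D plants over 1636 genes on chromosome 10 from 51898244 to 149031053, relative to the other chromosomes. In line 6Sa the ratio was 1.43 over 186 genes on chromosome 6 from 1 to 10312498, and in Dp4 the 4D plants had a ratio of 2.0 over 594 genes on chromosome 4 from 103631488 to 166653457. Full dosage would give 1.5, 1.5 and 2. The rest of these chromosomes stayed near 0 in log2 ratio (-0.01 in each line). There was 1 library per dose, so these ratios have no replicate check.

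Along the same chromosomes, expression stepped at the edges of the regions. In 10L18 the median log2 ratio of genes inside the region was -0.99 in 1D, 0.40 in 3D and 0.86 in 4D, while the rest of chromosome 10 lay at -0.08, -0.13 and -0.04. In 6Sa the 104 expressed genes of the region had medians of 0.51 in 3D and 0.74 in 4D, against -0.09 and -0.15 in the rest of chromosome 6. In Dp4 the 296 expressed genes of the segment reached 0.15 in 3D and 0.54 in 4D, against -0.15 and -0.17 in the rest of chromosome 4.

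**Figure D1:**
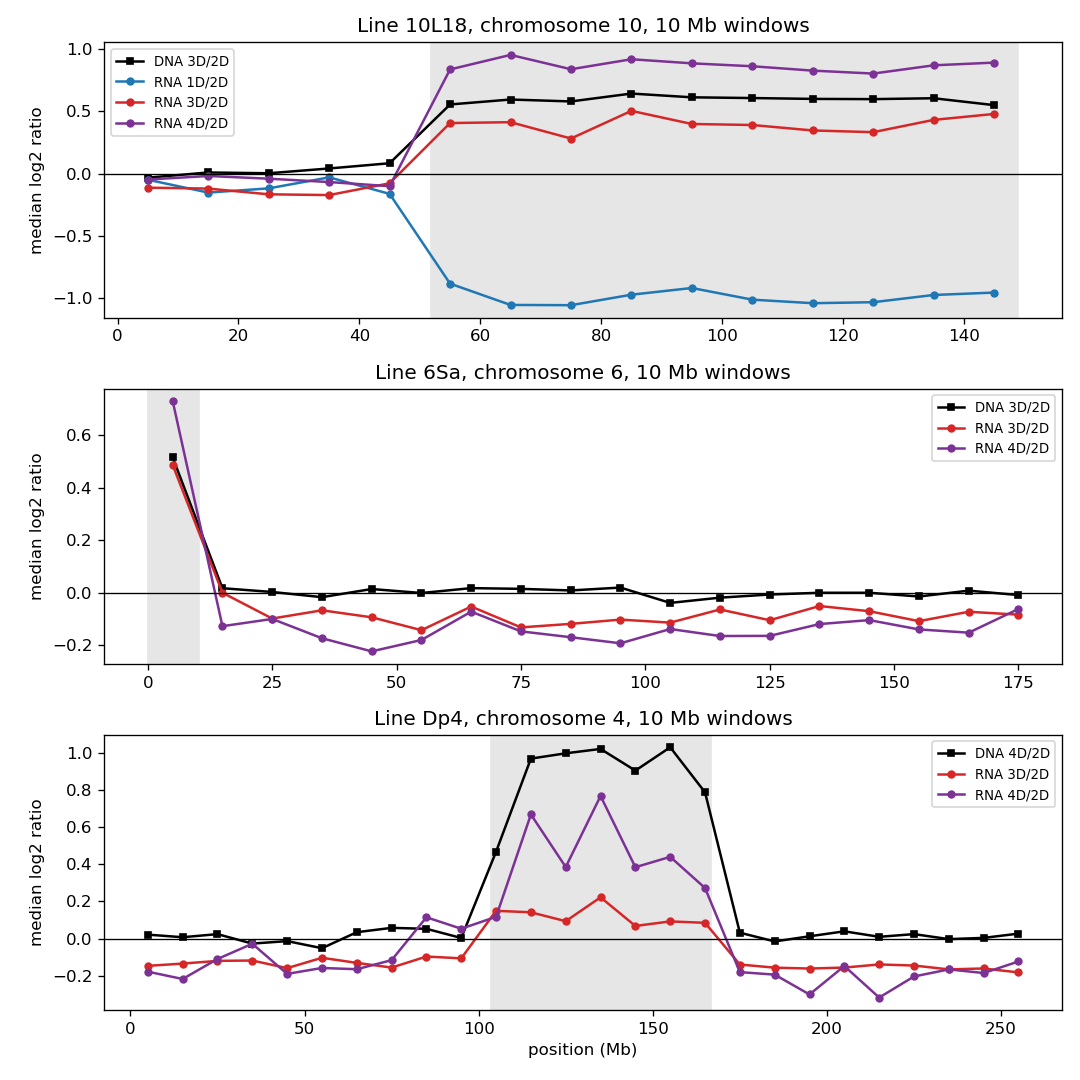
Median log2 ratio of DNA (RPKM) and RNA (FPKM) to 2D plants in windows of 10 Mb along the varied chromosome of lines 10L18, 6Sa and Dp4, with position in Mb on the x axis and the region set from DNA shaded. In 10L18 the RNA medians of the region are -0.99, 0.40 and 0.86 for 1, 3 and 4 copies, and in Dp4 the RNA lies below the DNA.

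Monosomy addressed how far genes follow the loss of 1 of 2 copies. Genes of the varied region fell in all 14 lines, to a mean median log2 ratio of -0.84 ± 0.14 (SD, n = 14), which is 0.56 of the diploid level (exact sign-flip permutation p = 0.000122 against 0, the smallest this test can give). The largest drop was in 5Lb (-1.13, 918 genes on the long arm of chromosome 5) and the smallest in 1Sb (-0.56, 1228 genes on the short arm of chromosome 1). Expression thus lay 0.16 above full dosage of -1 (same permutation test, p = 0.00110, above it in 13 of 14 lines). Much of the spread between lines was shared with genes elsewhere: relative to the trans median of the same line the change was -0.87 ± 0.04 (SD, n = 14), from -0.91 in 5Lb to -0.76 in 3Sb, again above -1 (permutation p = 0.000122). With a pseudocount of 0.05 the cis median lay only 0.09 above full dosage, and that difference no longer passed (permutation p = 0.0641).

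Single genes in monosomic regions mostly lay nearest to full dosage: a mean of 77.1% of expressed cis genes did so, 20.2% were nearest to no change and 2.74% to an inverse change. The share nearest to full dosage ran from 54.9% in 1Sb to 86.0% in 10L18. Noise in the group values also moves single genes between these levels, and the shares that noise alone would give were not computed. In the authors' deposited table, a mean of 63.2% of the tested cis genes were called lower in 1D, from 12.6% in 8Lc to 81.8% in 5Lb, and 1.68% were called higher.

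Trisomy raised the varied region in all 16 lines, with a mean median of 0.43 ± 0.10 (SD, n = 16), or 1.34 times the diploid level (exact sign-flip permutation p = 3.05e-05, the smallest this test can give). Every line lay below the 0.58 of full dosage, by a mean of -0.16 (same permutation test, p = 3.05e-05). The short arm of chromosome 1 (1Sb, 0.55) and that of chromosome 4 (4Sa, 0.52) were highest, and the chromosome 4 segment of Dp4 (0.15) and the long arm of chromosome 5 (5Lb, 0.24) lowest. Relative to the trans median the change was 0.48 ± 0.07 (SD, n = 16), from 0.28 in Dp4 to 0.60 in 6Sa, and 15 of 16 lines lay below full dosage (permutation p = 6.10e-05).

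In the trisomic regions a mean of 63.8% of expressed genes lay nearest to full dosage, 26.8% nearest to no change and 9.40% nearest to an inverse change. The levels lie closer together than in monosomy, so noise moves more genes between them. Its share was not computed, and the 26.8% is no measure of genes that did not respond to the added copy. Inverse changes were most frequent in 5Lb (24.3%) and 3Sb (20.7%), the lines compared with 2D plants of another line, and least frequent in 6Sa (2.88%). In the authors' deposited table a mean of 33.7% of tested cis genes were called higher in 3D, from 1.30% in Dp4 to 59.8% in 1Sb. Expressed as a share of full dosage, the cis response relative to trans did not differ detectably between the doses of a line (3D minus 1D -0.03 ± 0.08, SD, n = 14, p = 0.187, exact sign-flip permutation test).

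With 4 copies the regions of 5Sc, 6Sa and 10L18 reached median log2 ratios of 0.78, 0.74 and 0.86, while Dp4 reached 0.54. The mean was 0.73 ± 0.14 (SD, n = 4) where full dosage would give 1. Relative to the trans median the values were 0.91, 0.88, 0.92 and 0.67. The smallest p that 4 lines allow is 0.13, so no test was made. Between 4D and 3D plants, a comparison without the 2D control, the cis medians rose relative to trans by 0.37 in 5Sc, 0.35 in 6Sa, 0.42 in 10L18 and 0.38 in Dp4, where full dosage would give 0.42.

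**Figure D2:**
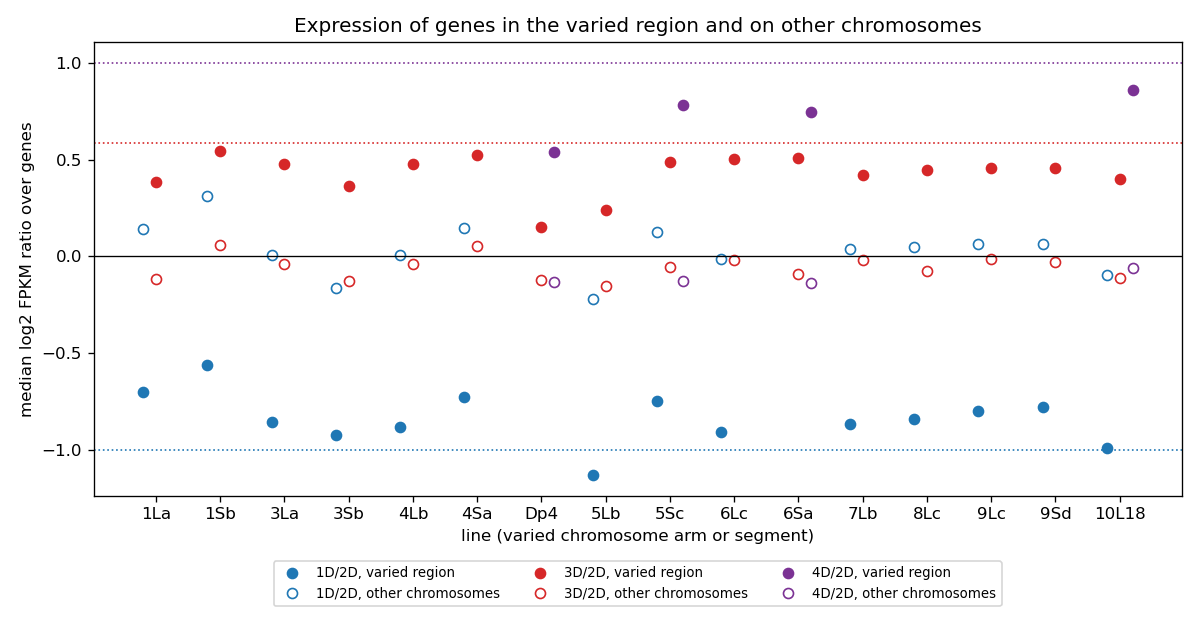
Median log2 FPKM ratio to 2D plants for genes in the varied region (filled circles) and on other chromosomes (open circles), for each line on the x axis and each dose by colour; dotted lines mark full dosage for 1, 3 and 4 copies. Cis medians lie between -1.13 and -0.56 in monosomies and between 0.15 and 0.55 in trisomies, and trans medians between -0.22 and 0.31.

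Genes on the other chromosomes moved much less than those of the varied region, and by different amounts in different lines. In monosomies the trans median was 0.03 ± 0.13 (SD, n = 14), above 0 in 10 of 14 lines and not different from 0 (exact sign-flip permutation p = 0.381). It was highest in 1Sb (0.31), 4Sa (0.14), 1La (0.14) and 5Sc (0.13), and lowest in 5Lb (-0.22) and 3Sb (-0.16). Without 3Sb and 5Lb, which share the 2D plants of 1Sb, the mean was 0.07 and above 0 (permutation p = 0.0269). In trisomies it fell below 0, at -0.06 ± 0.06 (SD, n = 16), in 14 of 16 lines (permutation p = 0.00345), with 1Sb (0.06) and 4Sa (0.05) as the exceptions. The values of 1Sb, 3Sb and 5Lb are not independent here either, since they share 2D plants. Without 3Sb and 5Lb the trisomy result kept its direction and its side of the threshold.

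Within a line, the trans median of 3D plants lay below that of 1D plants by a mean difference of -0.08 ± 0.10 (SD, n = 14), in 12 of 14 lines (exact sign-flip permutation p = 0.00500). Genes on the varied chromosome outside the region differed from trans genes by -0.02 ± 0.03 in monosomies (permutation p = 0.0170) and -0.01 ± 0.02 in trisomies (permutation p = 0.0201; SD, n = 14 and 16). In 1La and 9Lc the split taken from 3D left genes that were lowered in 1D outside the region; beyond the regions of both doses by at least 10 Mb the monosomy value was -0.01 ± 0.02 and no longer passed (permutation p = 0.0590), while the trisomies kept -0.01 (permutation p = 0.0133). In 4D plants the trans medians were -0.13 in 5Sc, -0.14 in 6Sa, -0.06 in 10L18 and -0.13 in Dp4.

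The spread of trans genes was widest in 5Lb and 3Sb, the lines compared with the 1Sb diploids. The interquartile range of trans log2 ratios was 0.53 ± 0.15 (SD, n = 14) in monosomies and 0.47 ± 0.17 (SD, n = 16) in trisomies, and reached 0.85 and 0.97 in 5Lb and 0.80 and 0.76 in 3Sb. In the ratio of 3D to 1D, which does not use those diploids, 3Sb and 5Lb had interquartile ranges of 0.51 and 0.52, inside the range of the other lines (0.36 to 0.76). The range did not differ detectably between 3D and 1D of a line (-0.04, n = 14, exact sign-flip permutation p = 0.152).

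Among single trans genes, a mean of 13.3% lay nearest to an inverse change in monosomies, 12.9% moved with the lost dose and 73.8% lay nearest to no change. In trisomies 23.5% lay nearest to an inverse change, 16.9% nearest to a change with the dose and 59.5% nearest to no change. The step between these levels is smaller for 3 copies than for 1, so the shares of the doses are not on 1 scale. Noise also places unchanged genes at either outer level, and how many was not computed. The shares are therefore no count of genes with a real inverse or direct response.

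The numbers of genes called in the authors' deposited table differed widely between lines. Monosomies had a median of 3237 called genes per comparison, from 407 in 8Lc to 9158 in 5Lb. Trisomies had a median of 1641.5, from 259 in 6Sa to 9538 in 5Lb, and the 4 tetrasomies a median of 1868.5, from 544 in 6Sa to 2979 in 10L18. Lines 3Sb and 5Lb were compared with the 2D plants of 1Sb, so their counts also hold differences between lines. Outside them the highest counts were 8721 in 1Sb monosomy and 5772 in 1La trisomy. In 1Sb monosomy 5889 trans genes were called higher and 1357 lower, whereas in 5Lb monosomy, set against the same 2D plants, 2161 were called higher and 5620 lower. In the authors' deposited table of 4D against 3D, 2340 genes were called in 10L18, 711 in 5Sc and 89 in 6Sa, and in Dp4 84 were higher and 117 lower.

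**Figure D3:**
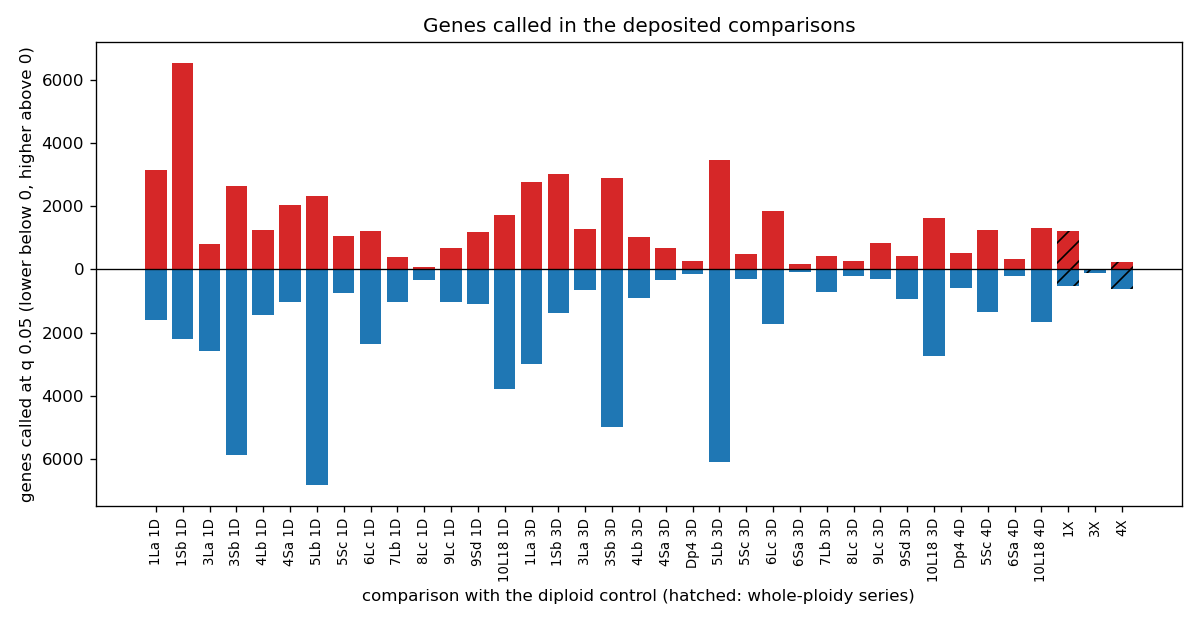
Number of genes with a deposited q-value under 0.05 in each comparison with the diploid control, those higher above 0 and those lower below 0; hatched bars are the whole-ploidy series. The dose series runs from 259 genes (6Sa, 3 copies) to 9538 (5Lb, 3 copies), and the triploids had 144.

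Calls in both doses of a line mostly went in opposite directions in cis genes and in the same direction in trans genes. The region of 1D was used for both doses here, so outside the lines with DNA it was chosen on the 3D ratio. Summed over 14 lines, 3490 cis genes were called lower in 1D and higher in 3D in the authors' deposited table, close to the 3247.61 of independent lists. Another 6 were higher in 1D and lower in 3D (10.2 for independent lists). Cis calls in the same direction were 116 higher in both (69.0) and 406 lower in both (363). Of the trans genes, 11434 were called lower in both doses and 6529 higher in both, against 4425.2 and 2027.77 for independent lists; 1616 were called higher in 1D and lower in 3D (2856.9 for independent lists) and 710 the reverse (2366.58). Without 3Sb and 5Lb the numbers were 3917 lower in both (1001.12 for independent lists) and 3301 higher in both (1332.54), and the opposite calls were 1457 and 617 (1449.13 and 676.93). These sums hide differences between lines: 10L18 gave 1995 of the 3917 and 1Sb 1330 of the 3301, and for genes higher in 1D and lower in 3D the counts were 411 in 6Lc (100 for independent lists) but 7 in 10L18 (250).

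Both doses share the 2D plants, which by itself makes their ratios move together. Across trans genes, which are not independent replicates, the correlation of 1D/2D with 3D/2D averaged 0.32 over lines. Simulated unchanged groups against a shared control gave 0.50. Equal noise in all groups fixes that value in advance, so the 0.32 cannot be judged by it. The covariance was 0.157 against a simulated 0.0318, and without 3Sb and 5Lb it was 0.0722 against 0.0335. The control plants could not be split, since each group has 1 value, so part of the excess may come from the shared control.

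Which genes moved in the same direction when different parts of the genome were lost or gained was tested across lines with limma. Across 14 monosomies 0 of 19237 trans genes passed (1743 at an unadjusted p under 0.05), and a robust variance trend also gave 0. Across 16 trisomies 48 of 19546 genes rose and 0 fell (1752 at an unadjusted p under 0.05); the median log2 ratio of the 48 was 1.80, and they lay on all 10 chromosomes, with 9 on chromosome 2 and 7 on chromosome 8. The largest was Zm00004b003246 (chromosome 1, 196278364 to 196283406), at 3.72 ± 0.45 (SE, limma adjusted p = 0.000388), higher in 13 of 14 lines. Next was Zm00004b025912 (chromosome 8, 89025991 to 89032079), at 3.36 ± 0.38 (SE, limma adjusted p = 0.000130), higher in 14 of 15 lines. Their sizes and order depended on the pseudocount. With 0.05 Zm00004b003246 stood at 5.99 and Zm00004b025912 at 4.07, and with 2 they stood at 2.31 and 2.38. With a minimum FPKM of 5 only 7 genes passed, all among the 48, and with 0.1 there were 127, including the 48.

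In the DNA of the 3D plants both genes were also higher than in 2D plants. In 10L18, DNA of Zm00004b025912 was 38.6 RPKM in 3D and 24.9 in 2D (ratio 1.55), and in 6Sa 24.9 and 9.27 (2.69); in Dp4 the ratio of 4D to 2D was 0.953. For Zm00004b003246 the DNA ratios were 1.44 in 10L18, 2.59 in 6Sa and 0.83 in Dp4. These DNA tables were normalized separately and have 1 library per dose.

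Over single lines, the 48 genes had a median log2 ratio between 0.54 (10L18) and 2.83 (9Sd) in the other trisomies. With the genes chosen again without Dp4, their median there was 0.00. Because 1D shares its 2D plants with the 3D ratios the genes were chosen on, the genes were chosen again without each line (and without 1Sb, 3Sb and 5Lb together) to measure its monosomy. The median was then 1.76 in 7Lb, 1.41 in 8Lc and 0.78 in 5Sc, each above all 10000 random lists matched on expression, 0.28 in 9Lc (percentile 99.4) and -2.04 in 10L18, below all of them; the other 9 monosomies lay inside the central 95%. The medians of the 48 were 0.00 in haploids, triploids and tetraploids, at percentiles 5.60, 99.0 and 87.8 of random lists. Fewer of the 48 were higher than lower in each, with 13 and 18 in haploids, 16 and 23 in triploids and 15 and 18 in tetraploids. The others had a log2 ratio of exactly 0, as genes at an FPKM of 0 in both groups have. These genes set the medians of 0.00, which are therefore no measure of an unchanged level. The random lists were matched on expression in the 2D and 3D groups of the trisomies, not on that in the ploidy groups.

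**Figure D4:**
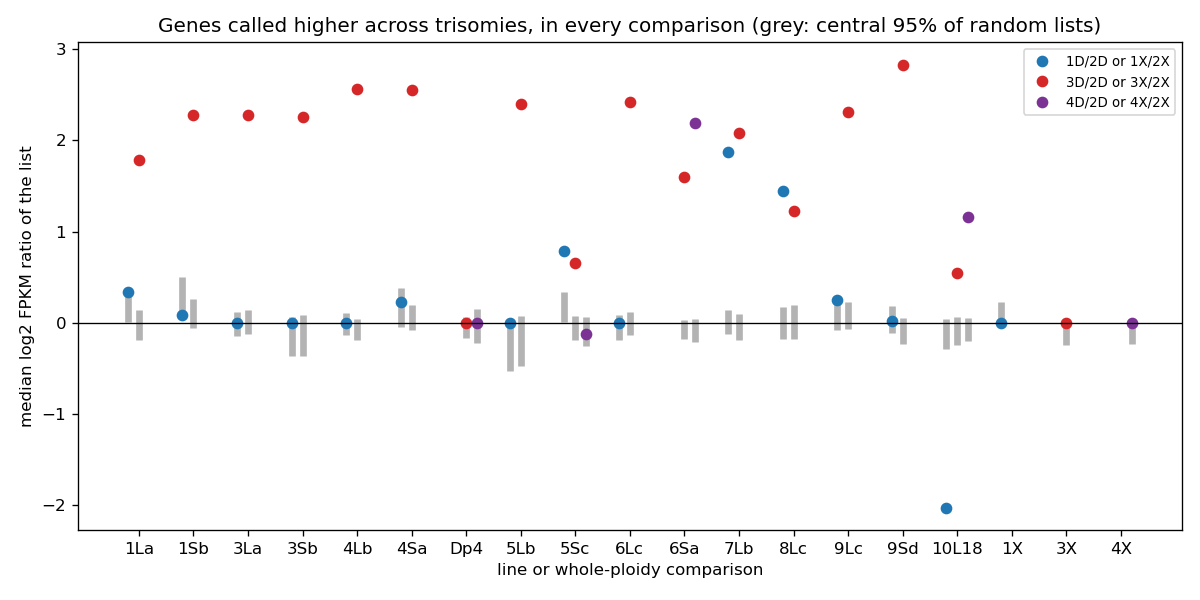
Median log2 FPKM ratio of the genes called higher across trisomies (chosen without Dp4 for Dp4), in every comparison on the x axis; grey bars are the central 95% of 10000 random gene lists matched on expression. The genes were chosen on these trisomies, and monosomies share their 2D plants. Trisomic medians lie between 0.54 and 2.83 outside Dp4. Those of Dp4 and the whole-ploidy series lie at 0.00, set by genes with a log2 ratio of exactly 0.

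The direct contrast of 3D over 1D, which leaves out the diploids, gave 31 of 19401 genes with limma, 28 higher and 3 lower (1870 at an unadjusted p under 0.05). Of the genes higher here, 25 were also among the 48, against 0.0675 for independent lists; both contrasts use the same 3D plants. Zm00004b003246 (3.63 ± 0.55, SE, limma adjusted p = 0.0246, higher in 11 of 12 lines) and Zm00004b025912 (3.54 ± 0.40, adjusted p = 0.00344, 12 of 13) were again the largest. Zm00004b004575 (chromosome 1, 260540703 to 260542939) fell by 0.98 (SE 0.17, adjusted p = 0.0434, lower in 12 of 12 lines) and Zm00004b017164 (chromosome 3, 111845563 to 111852010) fell by 0.62 (SE 0.11, adjusted p = 0.0474, lower in 12 of 12 lines). After centring each line on its trans median, 33 genes were higher and 0 lower; without 3Sb and 5Lb, 0 genes passed, and without any 1 of 10 lines (1Sb, 3La, 3Sb, 4Lb, 4Sa, 5Lb, 6Lc, 9Lc, 9Sd and 10L18) only 3 to 8 did.

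The size of the varied region was set against the response of trans genes, in 4 relations. Over 14 monosomies the trans median had a Pearson r of 0.34 with the number of expressed genes in the region (permutation p = 0.232, adjusted 0.386; Spearman rho 0.13, p = 0.648), and the interquartile range an r of -0.43 (p = 0.126, adjusted 0.386; rho -0.38, p = 0.187). Over 16 trisomies r was 0.28 for the median (p = 0.290, adjusted 0.386; rho 0.31, p = 0.239) and 0.03 for the interquartile range (p = 0.909, adjusted 0.909; rho 0.06, p = 0.815). None passed. Without the 2 lines farthest from the median size (3La and 3Sb for monosomy, Dp4 and 6Sa for trisomy) r was 0.26, -0.18, 0.12 and -0.22.

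Over all nuclear genes, those of the varied region included, fewer were called in triploids and tetraploids than in most changes of a single arm. In the authors' deposited table haploids had 1749 called genes, 1225 of them higher, tetraploids 855, of which 234 were higher, and triploids 144, of which 22 were higher. Of the 34 single-region comparisons, 13 had fewer calls than the haploids, 6 fewer than the tetraploids and 0 fewer than the triploids. The triploid comparison rests on 2 and 3 plants. These counts are not like for like, since those of single regions also hold calls in the varied region. Some also come from lines without 2D plants of their own, and a change shared by all genes is not visible in FPKM. Whether haploids had fewer calls than most single-region changes have in trans genes is therefore not decided by them. The median log2 ratio was 0.12 in haploids, -0.11 in triploids and -0.13 in tetraploids, and the interquartile ranges were 0.39, 0.29 and 0.49, with 8, 1 and 22 of the 34 single-region comparisons having a smaller range of trans genes. Within 1.5-fold of the diploid lay 87.5% of expressed genes in haploids, 93.8% in triploids and 81.2% in tetraploids.

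By chromosome, the medians were alike in haploids (0.11 to 0.13) and triploids (-0.11 to -0.10). In tetraploids chromosome 4 stood at -0.21, and the other 9 chromosomes between -0.14 and -0.11. There was 1 comparison per ploidy, so these values have no replicate check beyond the deposited q-values.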

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

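The test of abundant genes, the condition on single lines in the test of a fixed total, the triploids and the bound on size in the test of an added copy, and the tests of gene-poor regions and of extra copies in the 2D plants of Dp4 were chosen only after the result was seen.

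Trans medians lay below 0 in trisomies, at -0.06 on average over 16 lines. A few abundant genes taking more of the total are argued against as the whole cause: the change in the share of the top 1% of trans genes shifts the others by a mean of only -0.0057, and the remainder of -0.05 stayed below 0 (exact sign-flip permutation p = 0.000732, n = 16), although over lines that shift went with the trans median (r = 0.71, permutation p = 0.00203). An earlier form of this test, rescaling to the genes below the top 1%, gave -0.0085 (p = 0.571, permutation test) and was set aside because such rescaling centres the ratios whatever the cause. Open is the fixed total of the FPKM scale, which predicts a mean of -0.03 and leaves -0.025 (permutation p = 0.169), enough on the mean alone, the condition set at first, but over lines it ran the other way (r = -0.29, permutation p = 0.278), so it cannot be told apart from other causes. Also open is a biological one, the dose of the region acting on genes elsewhere, for which the relation of the trans median to the number of genes in the region decided neither way (r = 0.28, permutation p = 0.290).

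Among the 4 tetrasomic lines, Dp4 stood apart in its cis median minus trans median, at 0.67 where the others had 0.88 to 0.92, and its trisomy was also lowest (0.28, others from 0.40). A generally weak response of genes in gene-poor regions, such as those near centromeres, is argued against: over 12 other trisomies such genes lay only -0.011 from gene-rich parts of the region (bootstrap interval -0.06 to 0.03), where at least -0.11 would be needed, although single lines ran from -0.19 (1La) to 0.13 (4Sa). Plants with fewer copies among those pooled for 3D stay possible, since the spread of the segment's ratios lay at percentile 96.6 of equally long runs elsewhere, inside the central 95%. Extra copies among the pooled 2D plants may also account for it: 4D against 3D, which leaves them out, gave 0.38, within the other lines' 0.35 to 0.42. The single 2D plant with DNA gave a 4D ratio of 2.0, a shortage of copies would have to affect the 3D and 4D groups in like proportion, and no biological explanation beyond the gene density of the segment was tested.

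The 48 genes raised across trisomies may reflect reads from B-chromosome sequence carried by the translocation chromosome. In DNA of 3D plants of 10L18 and 6Sa the genes' median log2 ratios were 0.29 and 0.10, at percentiles of at least 99.95 among 10000 random lists, but the bootstrap interval of 6Sa held 0 (-0.01 to 0.23, 17 of 45 genes lower) and overlapped that of Dp4 (0.02, percentile 80.2, -0.09 to 0.24), so the support rests mainly on 10L18 (0.18 to 0.39). Against a rise of this size with an added copy of any part of the genome stand Dp4 and the triploids. With the genes chosen without Dp4 their median in Dp4 trisomy lay at percentile 67.2, with an upper bootstrap bound of 0.24. In triploids that bound was 0.00, whereas every trisomy other than Dp4 had at least 0.54. Neither decides the question. The copy difference between the pooled Dp4 plants is in doubt, as given above, and triploids gain all chromosomes together and rest on 2 and 3 plants. In triploids 16 of the 48 genes were higher and 23 were lower. The others had a log2 ratio of exactly 0, as genes at an FPKM of 0 in both groups have. Those genes hold the triploid median and its upper bound at 0.00, so neither measures how far the expressed genes of the list responded. The median of 0.00 lay at percentile 99.0 there only because random lists ranged from -0.24 to -0.01. That percentile is therefore no sign of a rise over diploids, while a small response relative to other genes is not excluded. With genes chosen without the line, RNA did not always follow the dose. Their median rose over 1D, 3D and 4D in 10L18 (-2.04, 0.54 and 1.17), but was 0.66 in 3D and -0.15 in 4D of 5Sc. It was raised in 1D of 7Lb (1.76) and 8Lc (1.41). By the medians of the list, RNA and DNA also ranked these lines differently, with RNA of 3D at 0.54 in 10L18 and 1.66 in 6Sa. DNA of the 2 named genes, picked as the largest in RNA, went the other way. Their ratios were 2.69 and 2.59 in 6Sa and 1.55 and 1.44 in 10L18, so the order of the lines in DNA depends on the genes taken. Which plants carried the translocation chromosome is not known here. No B-chromosome sequence was compared with these genes, and a transcriptional response to the B-chromosome part stays open.

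Of 100 draws of line signs, the real one included, 1 gave as many genes as the 48 of the trisomies, and the highest other draw gave 0, so by this count chance can be excluded there. The draws turned 1Sb, 3Sb and 5Lb separately, although they share 2D plants. Without 3Sb and 5Lb 36 genes passed, all higher, and no draws were made for that set of lines. For 3D over 1D, 2 of 100 draws, the real one included, gave at least the 31 genes, which is under the limit set beforehand. The other of these draws gave 635, far more than the real one. The 31 also became 0 without 3Sb and 5Lb and 3 to 8 without any 1 of 10 lines. Chance is therefore not excluded for 3D over 1D. The draw with 635 turned the signs of 3La, 3Sb, 4Lb, 6Lc, 8Lc and 9Lc. It was picked as the highest draw, and a difference between these lines and the others was not tested. For monosomies 0 genes passed, so the count of draws giving as many (100 of 100) is fixed beforehand and decides nothing; the highest other draw gave 1.

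Among the tetrasomic lines 10L18 also stood apart in its trans median, at -0.061 where the others lay at -0.13 and -0.14. In all, 4 measures were tested in this way, and chance marks about 1 in 20 such groups. The trans medians of trisomy and monosomy of a line differed, by -0.082 (exact sign-flip permutation p = 0.00500, n = 14). In Dp4 DNA, a window of chromosome 10 from 50 to 60 Mb outside the varied chromosome had a log2 ratio of -0.37 over 97 genes, where 6Sa had 0.00; RNA of 46 genes there stood at -0.49 in 4D, against a trans median of -0.13. The chloroplast gene psbA, a photosystem II core subunit, reached 15497 FPKM in 3D plants of 3Sb, 13739 in 1D plants of 3La and 9781 in 3D plants of 6Lc, but 12.04 in 1D plants of 3Sb, whereas the diploid groups ranged from 2.05 to 8675 in tables that were normalized separately. Predictions first written for the wide trans spread of 3Sb and 5Lb were withdrawn in favour of those for the 48 genes; the values they concern were computed all the same and are given above without weighing.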

How the results depend on the processing

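Alternatives added after seeing the data were the minimum RPKM for DNA, the tetrasomy settings, trisomy without 6Sa and Dp4, the pseudocounts for whole ploidy, and the rest of the varied chromosome beyond the regions of both doses. Over all summary results, 116 alternatives other than leaving out single lines kept direction and side of the threshold, 16 moved a value, 1 gained and 2 lost the threshold, and no result reversed. The monosomy trans median passed without 3Sb and 5Lb (0.070, p = 0.0269, permutation test); the monosomy cis median lay 0.086 from full dosage with pseudocount 0.05 and did not pass (p = 0.0641, permutation test), nor did the rest of the varied chromosome in monosomies beyond both regions (-0.011, p = 0.0590, permutation test). Monosomies gave 3 genes after centring. Trisomies gave 127 genes at FPKM 0.1 (126 higher) and 7 at FPKM 5, where fewer genes were tested. 3D over 1D gave 1 at FPKM 5, 17 with pseudocount 2 and 0 without 3Sb and 5Lb. At a q-value of 0.01 in the authors' deposited table, median calls were 2066.5 for monosomy, 883 for trisomy and 986 for tetrasomy, and calls were 837 in 1X, 79 in 3X and 385 in 4X, as a stricter threshold requires. Interquartile ranges with pseudocount 2 were 0.33 in 1X, 0.23 in 3X and 0.41 in 4X, and 0.34 in 1X at FPKM 5. Except where fewer genes or lines or a stricter threshold are named, the cause was not tested. Leaving out single lines gave 0.01 to 0.05 for the monosomy trans median, -0.86 to -0.81 for its cis median (0.14 to 0.19 from full dosage), -0.06 to -0.05 and 0.42 to 0.45 for trisomy (-0.17 to -0.14 from full dosage), and 0 to 5, 38 to 50 and 3 to 33 genes for monosomy, trisomy and 3D over 1D. For monosomy the lines that mattered were 1Sb (5 genes without it), 4Sa and 6Lc (2 each) and 4Lb (1); for 3D over 1D they were 3La, 4Lb, 9Lc and 9Sd (3 each), 3Sb (4), 4Sa, 6Lc and 10L18 (5 each), 5Lb (6) and 1Sb (8). Of the genes named for 3D over 1D, Zm00004b025912 lost the threshold only without 3Sb and 5Lb (3.34, limma adjusted p = 0.0684). The others lost it there too, at log2 ratios close to before, and in many other settings: Zm00004b004575 (-0.89, adjusted p = 0.301), Zm00004b017164 (-0.59, 0.222) and Zm00004b003246 (3.48, 0.209). Centring gave adjusted p values of 0.0603 and 0.180 for Zm00004b004575 and Zm00004b017164. No paired analysis was possible because the tables hold group values only, with no value per plant. For that reason the replicate block and leaving out each replicate were not run; the gene lists were not run for lack of names, and the minimum of 20 DNA reads for lack of counts. RNA depth is unknown, so its limit on low genes could not be set.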

Other observations

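The test of chromosome 4 in tetraploids was chosen only after the result was seen; the tests of shared responses were not.

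In tetraploids the genes of chromosome 4 lay lower than those of the other chromosomes, by a median log2 difference of -0.089 over 2010 expressed genes. This was the largest departure of an undisturbed chromosome among 336 measured in 37 comparisons, where the SD of the others was 0.01 and the next lowest was -0.06 (chromosome 10 in 4D plants of Dp4). The lower level ran along the whole chromosome, at -0.10 in the first part of its genes and -0.08 in the second, and the lowest such part of another chromosome in tetraploids was at -0.02. A hypothesis is that 1 of the 4 tetraploid plants lacked a copy of chromosome 4, leaving 15 copies of 16 in the group: that would give -0.093, and the bootstrap interval over genes of -0.11 to -0.07 holds it. A gained copy in 1 of the 4 diploid plants would give -0.17, outside that interval. The group has 1 pooled value, so plants could not be examined singly, and a difference in genetic background of chromosome 4 stays open.

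Whether different lines share a trans response was tested with pairs that use different 2D plants, over 19076 genes, which are not independent replicates. The mean correlation was 0.032 over 88 pairs of monosomies (sign-flip permutation p = 0.110, 47 pairs above 0) and 0.0079 over 117 pairs of trisomies (p = 0.549, permutation test, 61 above 0), and single pairs ran from -0.44 to 0.49 and from -0.36 to 0.37. For both, a response common to lines over all these genes cannot be told apart from none, since neither permutation test passed (SD of the sign flips 0.0237 and 0.0134). Such a correlation does not speak to small sets of genes, such as the 48 raised across trisomies. If loss and gain moved the same genes in opposite directions, pairs of a monosomy and a trisomy would correlate below 0; their mean was 0.0074 over 204 pairs (p = 0.224, permutation test). The haploid response had a mean correlation of 0.022 with the 14 monosomies (exact sign-flip permutation p = 0.762, 6 above 0), which leaves a resemblance undecided.

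In single lines the genes raised across trisomies stood in different orders over the doses, measured with the genes chosen without the line. In 10L18 they stood at -2.04 in 1D, 0.54 in 3D and 1.17 in 4D relative to 2D, and in 5Sc at 0.78, 0.66 and -0.15. In 6Sa they stood at 1.66 in 3D and 2.24 in 4D.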
